A study of Mus musculus with 18 samples.

How the data were processed

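Total RNA of 18 snap-frozen kidneys of male mice was hybridised to Illumina MouseWG-6 v2 bead arrays, 1 array per mouse, per the labels' protocols. The labels form 3 groups of 6 biological replicates. The sham mice had the right kidney removed and the left pedicle exposed but not clamped. The ischaemic controls and the ischaemic ΔN mice had the same operation with a clamp of 17.5 min and were examined after 24 h of reperfusion. ΔN stands for a truncated form of the NF-κB inhibitor IκBα, placed in the Ctnnb1 gene behind a stop that Cre removes, with Cre driven from the Emx1 gene in tubule cells. All 6 ΔN mice carry both alleles. The control group holds 3 mice labelled wild type, 2 with Cre alone and 1 with the ΔN allele alone, and the sham mice are all labelled wild type.

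The deposited value per probe and array is an intensity on a linear scale, and the submitters' processing notes name GenomeStudio with no version. The background correction and the normalization of the authors are not given in the sources used here. In the deposited values, the quantiles of each of the 18 arrays lay within 0.330 intensity units of their mean over the arrays. The values had thus already been brought to 1 distribution before deposit. They run from 49.5 to 50641.67, and detection p-values were not used here. The intensities were taken to log2 with no offset, no further normalization and no filter. All columns of the value table were used.

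Of 45281 probes, the platform annotation gives 1 gene symbol to 34885, several to 18 and none to 10378, for 19057 genes. By Entrez number, 34807 of the probes with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, all with an equal symbol, and this table was used only for names and for which genes neighbour each other. A gene was represented by its probe with the highest mean over all 18 arrays. Background was set at the 95th percentile of the mean of 1287 probes for olfactory receptor genes, an intensity of 108. Above it lay 22288 probes (49.2%) and 11726 genes. Where a probe was not above background in any array of a group, the fold is a bound ("at least"), computed against the higher of background and the probe's own value in each array of that group. For Sprr2g, Chil3, Il11 and Mcm3 in sham and Tmem207, Cxcl2 and Ccl2 in ΔN kidneys the group mean was below background but not every array, so that their differences hold part of the background. The number of arrays limits the precision.

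Probes were compared between groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on all 18 arrays with group means and no block. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Standard errors (SE) are those of limma. For 33 gene lists, limma's camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the lists. The lists cover tubular injury, NF-κB targets, chemokines and cytokines, acute phase genes, complement, the interferon response, markers of neutrophils, of monocytes and macrophages, of dendritic cells, of T and NK cells, of B cells, of endothelium, of fibroblasts and matrix, of the nephron segments (proximal tubule, thick ascending limb, distal tubule, principal cells, intercalated cells, podocytes), fatty acid oxidation, oxidative phosphorylation, glycolysis, p53 targets, cell death, the cell cycle, immediate early genes, heat shock, Nrf2 targets, the unfolded protein response, hypoxia, Wnt targets, blood, and fat with adrenal tissue. Of 629 entries, 576 were measured, and genes absent from the annotation are not analysed here. The response to ischaemia in the ΔN kidneys was compared with that in the controls by cross-fitting. Probes were chosen and signed with 3 of the controls against sham, and the ΔN kidneys were set against the other 3 controls, over all 20 choices.

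The text names the 10 genes with the largest rise and the 10 with the largest fall per comparison, among those past the threshold, with the same direction on each of the 3 array chips and above background in a group compared. It also names Nfkbia, Ctnnb1, Emx1, Havcr1, Lcn2, Tnfaip3, Cxcl1, Ccl2, Icam1, Vcam1, Cxcl10, S100a8, Umod and Slc34a1 in every comparison, and examples from the 4 members of each list with the smallest p. Groups, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined, while cyclic loess, a second centring, leaving out the 2 outlying ischaemic kidneys, leaving out single arrays for the lists and single controls for the response, and the response at probes called in all 12 ischaemic kidneys were added later.

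Each of the 3 chips holds 2 arrays of each group, so chip effects do not follow the groups, and values per chip and with the chip as a block are given where they matter. Sham arrays always took positions 5 and 6 of a chip and ischaemic arrays positions 1 to 4, so that position and surgery cannot be told apart. The alternatives were the chip or the replicate number as a block, each chip alone, 2 offsets, a filter on dim probes, array weights, a variance trend, a fit of only the groups compared, Welch's test, stricter thresholds, median centring, cyclic loess, controls of 1 genotype, array position as a block, and each array left out. For lists they were camera with an estimated correlation, fry, and an exact 2-sided permutation test of the list mean over all splits of the 12 arrays, whose smallest p is 0.00216.

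The scripts were tested on simulated data with 200 changed probes among the 45281, set up like the comparison of ΔN with control kidneys. The fit on 18 arrays recovered 36.0% of changes of 1.25-fold, 94.0% of 1.5-fold and 100% of 2-fold or more, and 42 of its calls (20.3%) were false. The fit on the 12 ischaemic arrays recovered 24.0%, 84.0% and 96.0%, with 15 false calls (8.98%). Simulated kidneys with no ΔN effect gave a cross-fitted difference of 0.158% of the response, against -3.28% without splitting the controls, and with 10% of each change removed it was -9.56%. Each probe was drawn independently, so that no simulated kidney shifted as a whole, as real kidneys can. These percentages thus test for bias and do not show how far the difference strays by chance between real kidneys. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.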

Results

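Expression was measured in 18 mouse kidneys in 3 groups of 6 mice, which were sham-operated, ischaemic control and ischaemic ΔN kidneys. The comparisons address what tubular inhibition of NF-κB changes in the kidney 24 h after ischaemia. The median intensity of each array was near 107. Ischaemic and sham kidneys parted on the first principal component, which held 66.4% of the variance. The median SD per probe was 0.12 log2 in sham, 0.18 in control and 0.16 in ΔN kidneys. 1 control kidney (replicate 2, the mouse with the ΔN allele alone) had the lowest mean correlation with its own group, 0.975.

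The alleles of the model were looked at first. Ctnnb1, which encodes β-catenin and hosts the inserted ΔN sequence, lay at a log2 level of 12.55 ± 0.21 (SD, n = 6) in sham, 12.69 ± 0.31 in control and 12.15 ± 0.20 in ΔN kidneys. ΔN minus control was -0.54 (SE 0.13, adjusted p = 0.200), and 2 of the 3 other Ctnnb1 probes above background had the same sign. The control with the ΔN allele alone (replicate 2) was at 12.10, within the range of the ΔN kidneys (11.85 to 12.35), and the other controls at 12.63 to 12.99. Between the 7 ischaemic kidneys with the allele and the 5 without it the difference was -0.67 (limma adjusted p = 0.0637), a grouping chosen after the data were seen. Nfkbia, which encodes IκBα itself, was at 9.37 ± 0.08 in sham, 9.94 ± 0.27 in control and 9.58 ± 0.23 in ΔN kidneys. Whether its probes read the truncated product is not given in the sources used here, so that Nfkbia does not check the label. Emx1, a homeobox gene whose locus drives Cre, was at 8.60 ± 0.14 in sham, 7.43 ± 0.23 in control and 7.40 ± 0.10 in ΔN kidneys.

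Ischaemia changed the control kidney widely. The largest rises against sham were those of 3 genes of the tubular injury list. Havcr1, which encodes the injury receptor KIM-1, rose 134-fold (log2 7.07, SE 0.15, adjusted p = 6.6e-18, n = 6 per group). Lcn2, which encodes the iron-trapping protein NGAL, rose 88.8-fold (log2 6.47, SE 0.20), and the keratin gene Krt20 rose 66.8-fold (log2 6.06, SE 0.18). The largest falls were those of Nccrp1 (log2 -4.06, SE 0.29), the brush-border protease gene Mep1b (-3.76, SE 0.22), the growth factor gene Egf (-3.67, SE 0.30) and Pvalb, a calcium buffer of the distal tubule (-3.66, SE 0.20).

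Of all probes, 12375 (27.3%) changed between control and sham kidneys, 6123 upward and 6252 downward, at 6648 genes. At least 2-fold changes were seen in 851 probes upward and 884 downward. With 1 chip at a time, which leaves 2 arrays per group, 4459, 7137 and 7284 probes passed. Among the largest rises were also Timp1, an inhibitor of matrix proteases (log2 5.10, SE 0.19), Sprr2g, a cornified envelope gene (4.80, SE 0.30, with a sham mean of 6.54, below the background of 6.75), and Sox9, a transcription factor of regenerating tubules (4.74, SE 0.32). Fgg, a fibrinogen chain gene (3.86, SE 0.16), and Cxcl1, a neutrophil attractant (3.83, SE 0.18), completed them together with Sprr2f and the filamin gene Flnc. Sprr2f rose at least 20.6-fold and Flnc at least 16.7-fold, since neither was above background in sham. Further large falls were those of Mettl7a2 (-3.44, SE 0.34), the organic anion transporter genes Slc22a22 (-3.19, SE 0.18) and Slc22a19 (-3.02, SE 0.35), the carbonic anhydrase gene Car14 (-3.12, SE 0.16) and Fam107a (-3.08, SE 0.13). Cox8b, a cytochrome oxidase subunit of heart, muscle and brown fat, fell at least 8.50-fold.

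The tubular injury list had 22 measured members, of which 21 rose and 0 fell by limma (median log2 change 2.27). All 22 had unadjusted changes above 0, and 21 passed adjusted over the list alone. Besides Havcr1, Lcn2 and Krt20, the cytokine receptor gene Tnfrsf12a rose by 3.55 on the log2 scale. Against all other genes the list was raised (camera adjusted p = 1.0e-23, and adjusted p = 0.0145 with an estimated correlation).

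Targets and mediators of inflammation rose. Of 31 NF-κB targets, 24 rose and 2 fell (26 and 2 adjusted over the list alone, median 0.57). Nfkbiz, an atypical IκB, rose by 1.97 on the log2 scale, the subunit gene Relb by 1.38 and the adhesion molecule gene Icam1 by 1.21 (SE 0.08). Vcam1 rose by 0.73 (SE 0.14), Nfkbia by 0.57 (SE 0.11, adjusted p = 3.1e-04) and Tnfaip3, a feedback inhibitor, by 0.29 (SE 0.10, adjusted p = 0.0269). Tnfaip3 did not pass without control replicate 1 or 3 or sham replicate 2, 3 or 4 (adjusted p = 0.0775, 0.0538, 0.0576, 0.0675 and 0.0636), or with only the 3 controls labelled wild type (adjusted p = 0.0596). Ccl2, a monocyte attractant, rose at least 1.10-fold, and Cxcl10 at 0.34 did not pass (SE 0.14, adjusted p = 0.0847), though it did with the wild-type controls alone (0.53, adjusted p = 0.0189). Of 36 chemokines and cytokines, 22 rose and 3 fell (23 and 4 adjusted over the list alone), among them Il34 (2.13) and Il11 (2.45). Of 22 acute phase and STAT3 genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with Socs3 at 3.29 and the fibrinogen gene Fga at 3.73. These 3 lists were raised against all other genes (camera adjusted p = 5.8e-10, 6.9e-06 and 1.0e-07, and adjusted p = 0.0145, 0.0431 and 0.0255 with an estimated correlation).

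Markers of white blood cells went different ways. Of 19 neutrophil markers 9 rose and 0 fell by limma (10 and 0 adjusted over the list alone). S100a8, a neutrophil calcium-binding protein gene, rose by 3.11 (SE 0.36), with 4.56, 3.29 and 1.49 on the 3 chips. The list passed by camera (adjusted p = 0.00366), but not with an estimated correlation (adjusted p = 0.269). Of 22 monocyte and macrophage markers 11 rose and 2 fell (12 and 2 adjusted over the list alone). The endotoxin co-receptor gene Cd14 rose by 2.59 and Chil3 by 3.22, while the CSF1 receptor gene Csf1r fell by 0.81 (camera adjusted p = 0.00611, and adjusted p = 0.331 with an estimated correlation). Of 14 dendritic cell and MHC class II genes 6 fell and 0 rose by limma (6 and 0 adjusted over the list alone), with H2-Eb1 at -1.44 and Cd74 at -1.14 (camera adjusted p = 0.00232, and adjusted p = 0.175 with an estimated correlation). T and NK cell markers (2 rose and 2 fell of 17, camera adjusted p = 0.745) and B cell markers (0 rose and 1 fell of 9, adjusted p = 0.686) did not pass. Neither did complement (0 rose and 4 fell of 13, adjusted p = 0.246) or the interferon response (3 rose and 3 fell of 24, adjusted p = 0.777).

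Transcripts of the nephron fell, most widely in the proximal tubule, where 23 of 27 members fell and 1 rose (24 and 2 adjusted over the list alone, median -1.09). Miox, an enzyme of inositol breakdown, fell (log2 -1.59), as did the anion transporter gene Slc22a8 (-1.72) and the phosphate transporter gene Slc34a1 (-0.85, SE 0.06). The list passed by camera (adjusted p = 2.1e-13, and adjusted p = 0.0255 with an estimated correlation). Of 13 genes of the thick ascending limb 10 fell and 0 rose (10 and 1 adjusted over the list alone), while Umod, its most abundant secreted protein, stood at -0.05 (SE 0.09, adjusted p = 0.763). This list's adjusted p was 1.1e-05, and adjusted p = 0.138 with an estimated correlation. Of 11 distal tubule genes 5 fell and 0 rose, with the kinase gene Wnk1 at -1.04 and the sodium-calcium exchanger gene Slc8a1 at -1.72 (camera adjusted p = 0.00209, and adjusted p = 0.0940 with an estimated correlation). Of 12 intercalated cell genes 8 fell and 0 rose, with the anion exchanger gene Slc4a1 at -2.25 (adjusted p = 0.00177, and adjusted p = 0.112 with an estimated correlation). Adjusted over the list alone, the counts of these 2 lists were again 5 and 8. Principal cell genes (3 fell and 0 rose of 11, adjusted p = 0.298) and podocyte genes (2 rose and 2 fell of 8, adjusted p = 0.641) did not pass.

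Stress response genes rose. Of 15 Nrf2 targets 12 rose and 0 fell (13 and 0 adjusted over the list alone), led by the haem oxygenase gene Hmox1 (3.82) and Srxn1 (2.60). Of 15 genes of the unfolded protein response 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Trib3 at 3.47 and the asparagine synthetase gene Asns at 3.08. Of 13 heat shock genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Hspb1 at 3.09. Of 18 cell death mediators 9 rose and 0 fell (10 and 0 adjusted over the list alone), with Mlkl, the effector of necroptosis, at 2.84. These 4 lists passed by camera (adjusted p = 4.5e-08, 8.8e-05, 0.00155 and 9.9e-04) and with an estimated correlation (adjusted p = 0.0180, 0.0145, 0.0462 and 0.0324).

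Immediate early genes (16 rose and 0 fell of 18, Junb at 2.43), cell cycle genes (16 rose and 0 fell of 24, the replication gene Mcm5 at 2.01), p53 targets (8 rose and 2 fell of 17, the cell cycle inhibitor gene Cdkn1a at 3.29) and glycolysis (6 rose and 0 fell of 14) were raised by camera (adjusted p = 8.2e-10, 7.6e-06, 0.0218 and 0.0170). None of these 4 lists passed with an estimated correlation (adjusted p = 0.0538, 0.128, 0.105 and 0.0532). Fibroblast and matrix genes were raised as well (11 rose and 2 fell of 17, Col4a1 at 1.37, adjusted p = 0.00366, and adjusted p = 0.364 with an estimated correlation). Oxidative phosphorylation (16 fell and 1 rose of 29), fatty acid oxidation (8 fell and 3 rose of 19, with the regulator Ppargc1a at -1.02) and blood markers (4 fell and 0 rose of 7) were lowered by camera (adjusted p = 9.0e-05, 0.0159 and 0.0339). With an estimated correlation none of these 3 passed (adjusted p = 0.113, 0.258 and 0.320), and blood markers were lost without control replicate 2, sham replicate 4 or sham replicate 5 (adjusted p = 0.0593, 0.0503 and 0.0528). With only members that stand in no other list, blood markers and glycolysis did not pass (adjusted p = 0.140 and 0.0594). Endothelial markers (2 rose and 1 fell of 18, adjusted p = 0.686), hypoxia genes (2 rose and 5 fell of 16, adjusted p = 0.403), Wnt targets (1 rose and 5 fell of 14, adjusted p = 0.116) and fat with adrenal markers (0 rose and 3 fell of 11, adjusted p = 0.0685) did not pass. Adjusted over the list alone, the counts up and down were 16 and 0 for immediate early genes, 16 and 0 for the cell cycle, 8 and 3 for p53 targets, 6 and 0 for glycolysis, 11 and 3 for fibroblasts, 1 and 18 for oxidative phosphorylation, 3 and 10 for fatty acid oxidation and 0 and 5 for blood.

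**Figure D1:**
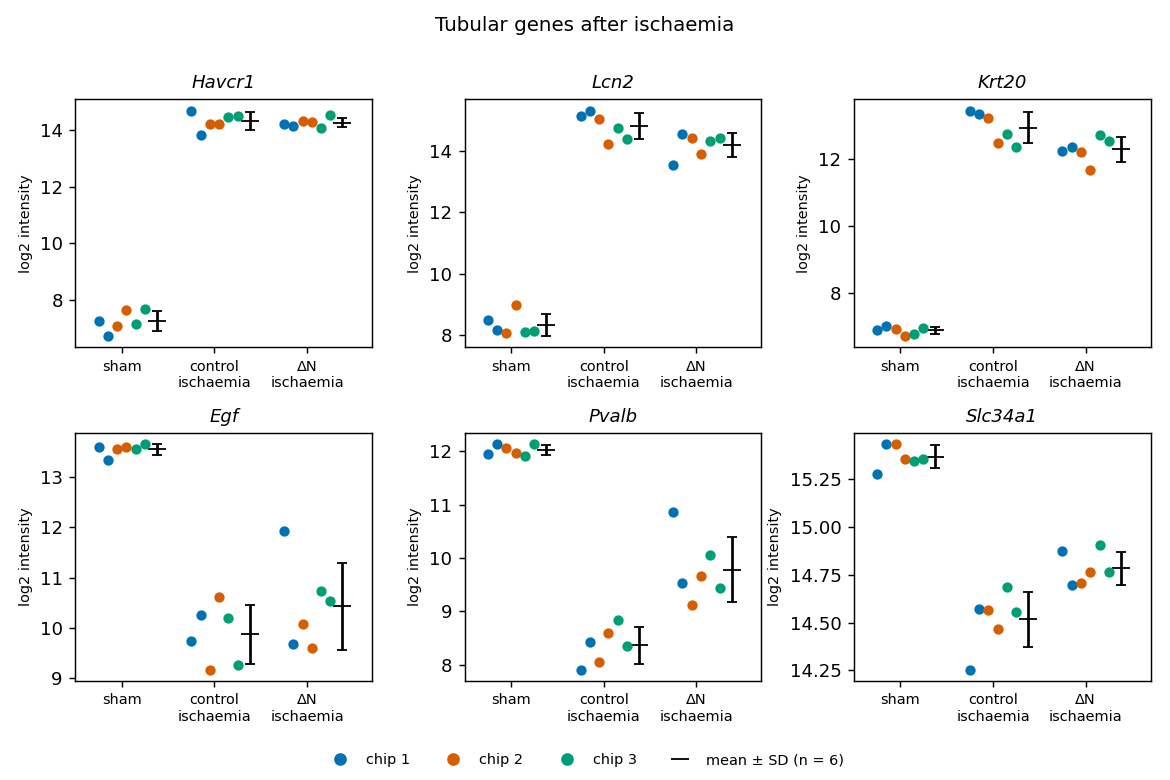
Log2 intensity of 6 genes in each of the 18 kidneys, by group; points are single kidneys, coloured by array chip, and black bars are group means with SD. Havcr1, Lcn2 and Krt20 are higher in all ischaemic than in all sham kidneys, and Egf, Pvalb and Slc34a1 are lower.

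The ischaemic ΔN kidneys were then set against the ischaemic controls, which asks what the inhibitor changes in the injured kidney. 5 genes were higher in ΔN kidneys, and 0 were lower by limma. They were Pvalb (log2 1.42, SE 0.20, 2.67-fold, adjusted p = 0.0128), Hhatl (0.96, SE 0.15, adjusted p = 0.0229), the potassium channel subunit gene Kcne1 (0.72, SE 0.09, adjusted p = 0.00350), Syt7, a sensor of calcium-driven exocytosis (0.58, SE 0.08, adjusted p = 0.00896), and Vstm2a, at least 1.21-fold higher (adjusted p = 0.0469), with n = 6 per group. Pvalb lay at a log2 level of 12.03 ± 0.10 (SD) in sham, 8.36 ± 0.35 in control and 9.78 ± 0.61 in ΔN kidneys. On the 3 chips Pvalb differed by 2.02, 1.07 and 1.16, Hhatl by 1.31, 0.74 and 0.84, Kcne1 by 0.74, 0.88 and 0.54, Syt7 by 0.76, 0.40 and 0.59, and Vstm2a by 0.53, 0.30 and 0.35. Of the 2 other Vstm2a probes above background only 1 had the same sign, while all 3 of Kcne1 had. Pvalb, Hhatl and Syt7 had 0 other probes above background.

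At an unadjusted p under 0.05, 3347 probes (7.39%) differed, 1690 upward and 1657 downward. A test of each probe by itself and a fit of only these 2 groups called 0 probes after adjustment, against 5 by the fit of all groups. In the simulated data 20.3% of the calls were false in the fit of all groups, above the threshold of 0.05. Without control replicate 3 the count was 2, and without control replicate 5 it was 9 (6 higher and 3 lower in ΔN kidneys). Without control replicate 6 it was 17 (14 higher and 3 lower), and without ΔN replicate 2 it was 3. Against the 3 controls labelled wild type alone none of the 5 genes passed (adjusted p = 0.0585 for Pvalb and Kcne1, 0.106 for Syt7, 0.168 for Vstm2a and 0.224 for Hhatl), and with the chip as a block Vstm2a did not (adjusted p = 0.0795). Kcne1 and Syt7 passed without any single array. Pvalb did not pass without control replicate 3 (adjusted p = 0.0617), and Hhatl did not without control replicate 3 or 4 or ΔN replicate 2 or 5 (adjusted p = 0.0894, 0.0686, 0.0797 and 0.0595). Vstm2a did not without control replicate 1, 2, 3 or 4 (adjusted p = 0.167, 0.0838, 0.0894 and 0.0833) or ΔN replicate 1, 2, 3 or 5 (adjusted p = 0.129, 0.0693, 0.123 and 0.0941).

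None of the 14 genes named in every comparison passed between ΔN and control kidneys in limma, where 3347 of all probes (7.39%) had an unadjusted p under 0.05. Among the latter were the probes of Ctnnb1, Vcam1, S100a8, Nfkbia, Lcn2, Icam1 and Ccl2, all lower in ΔN kidneys, and of Slc34a1, which was higher. Those of Emx1, Havcr1, Tnfaip3, Cxcl1, Cxcl10 and Umod were not among them. Lcn2 stood at -0.62 (SE 0.20, adjusted p = 0.410), Vcam1 at -0.54 (SE 0.14, adjusted p = 0.254), Nfkbia at -0.36 (SE 0.11, adjusted p = 0.377), Icam1 at -0.21 (SE 0.08, adjusted p = 0.568), Cxcl1 at -0.30, Ccl2 at -0.19, Tnfaip3 at -0.17 and Cxcl10 at 0.25. S100a8 stood at -1.29 (SE 0.36, adjusted p = 0.311), with -2.39, -1.45 and -0.02 on the 3 chips. Havcr1 stood at -0.05, Umod at 0.05, Slc34a1 at 0.27 (adjusted p = 0.213) and Emx1 at -0.02.

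As groups, 17 of the 33 lists differed by camera with the preset correlation, 6 upward and 11 downward, and 0 did with an estimated correlation, where the lowest adjusted p was 0.0556. The tool fry called 4 (NF-κB targets, acute phase, distal tubule and intercalated cells). The exact permutation test of the list means called 0 after adjustment and 7 at an unadjusted p under 0.05.

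NF-κB targets were lower in ΔN kidneys by camera with the preset correlation, though not with an estimated one (adjusted p = 0.0556). Of their 31 members 0 passed over all probes in limma, 26 were below 0, and 8 were lower and 1 higher adjusted over the list alone. The list mean differed by -0.18 log2, and by -0.31, -0.14 and -0.08 on the 3 chips (camera adjusted p = 2.1e-07). The exact permutation p was 0.0108, and 0.0893 adjusted over the lists. The neutrophil attractant gene Cxcl2 stood at -0.65 (adjusted p = 0.0840, 0.0417 with a variance trend, and 4.2e-04 adjusted over the list alone), Relb at -0.35 and Nfkbiz at -0.45. Acute phase genes had a mean of -0.28 (-0.50, -0.26 and -0.08 by chip), with 8 of 22 lower adjusted over the list alone and Fga at -0.65 (camera adjusted p = 2.3e-07, and adjusted p = 0.0556 with an estimated correlation). Distal tubule genes had a mean of 0.32 (0.41, 0.15 and 0.40 by chip). Besides Pvalb, which passed over all probes, Tmem52b (0.51), Wnk1 (0.31) and Slc8a1 (0.64) were higher adjusted over the list alone, 4 of 11 in all (camera adjusted p = 2.2e-06, and adjusted p = 0.0556 with an estimated correlation). Intercalated cell genes had a mean of 0.24 (0.43, 0.14 and 0.15 by chip), with 4 of 12 higher adjusted over the list alone, among them Slc4a1 (0.93) and the ammonia transporter gene Rhcg (0.56) (camera adjusted p = 4.6e-05, and adjusted p = 0.109 with an estimated correlation).

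Among the other lists called by camera, the shifts were largest on the first chip for most. Tubular injury genes had a mean of -0.32 (-0.67, -0.23 and -0.07 by chip), with 6 of 22 lower adjusted over the list alone (adjusted p = 2.3e-07, and adjusted p = 0.165 with an estimated correlation). Immediate early genes had a mean of -0.33 (-0.74, -0.21 and -0.04), with 6 of 18 lower adjusted over the list alone and Junb at -0.58 (adjusted p = 1.6e-09, and adjusted p = 0.109 with an estimated correlation). Neutrophil markers had a mean of -0.35 (-0.71, -0.31 and -0.03), with 6 of 19 lower adjusted over the list alone (adjusted p = 1.6e-05, and adjusted p = 0.210 with an estimated correlation). Endothelial markers had a mean of -0.21 (-0.36, -0.40 and 0.13), with 1 of 18 lower adjusted over the list alone (adjusted p = 2.2e-05, and adjusted p = 0.331 with an estimated correlation). Proximal tubule genes had a mean of 0.19 (0.32, 0.20 and 0.04), with 4 of 27 higher adjusted over the list alone (adjusted p = 3.0e-05, and adjusted p = 0.241 with an estimated correlation). The thick ascending limb had a mean of 0.27 (0.45, -0.06 and 0.41), with 1 of 13 higher adjusted over the list alone (adjusted p = 1.6e-04, and adjusted p = 0.316 with an estimated correlation).

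Cell cycle genes had a mean of 0.15 (0.38, 0.23 and -0.17 by chip), and dendritic cell and MHC class II genes had a mean of 0.15 (0.37, 0.09 and -0.01). Of neither list did a member pass adjusted over the list alone (camera adjusted p = 8.0e-04 and 0.00557, and adjusted p = 0.331 and 0.316 with an estimated correlation). Chemokines and cytokines had a mean of -0.08, monocyte and macrophage markers of -0.14, fibroblast and matrix genes of -0.12, heat shock genes of -0.16 and the unfolded protein response of -0.09. Their camera adjusted p-values were 0.0108, 0.0195, 0.0272, 0.0418 and 0.0456, and with an estimated correlation adjusted p = 0.310, 0.472, 0.565, 0.245 and 0.210. Adjusted over the list alone, 5 chemokines and 3 macrophage markers were lower, and 1 chemokine (Ccl20, 0.38) was higher. In the heat shock, fibroblast and unfolded protein response lists no member passed. Without single arrays these 5 calls and that of the cell cycle were lost: chemokines without control replicate 6 or ΔN replicate 1 (adjusted p up to 0.120), macrophage markers without control replicate 3 or 6 or ΔN replicate 1, 3 or 4 (up to 0.223), and fibroblast genes without control replicate 2 or 3 or ΔN replicate 1, 3, 4 or 6 (up to 0.382). Heat shock genes were lost without control replicate 2 or 3 or ΔN replicate 1 or 2 (up to 0.216), the unfolded protein response without control replicate 4 or 6 or ΔN replicate 2, 3 or 5 (up to 0.167), and the cell cycle without ΔN replicate 2 (0.0708). Against the 3 controls labelled wild type alone, 7 of the 17 camera calls were lost: endothelial markers (adjusted p = 0.601), proximal tubule (0.0714), dendritic cells (0.0732), cell cycle (0.176), macrophage markers (0.0714), heat shock (0.316) and fibroblast genes (0.796, with the direction turned to higher in ΔN kidneys). Without both outlying ischaemic kidneys (control replicate 2 and ΔN replicate 1) 5 were lost: endothelial markers (adjusted p = 0.104), macrophage markers (0.107), chemokines (0.0699), heat shock (0.209) and fibroblast genes (0.819). With the chip as a block heat shock and the unfolded protein response did not pass (adjusted p = 0.0516 for both). Chemokines did not pass with only members above background (0.112) or in no other list (0.151), the unfolded protein response with only members above background (0.0649), nor heat shock with the mean of the probes of each gene (0.0571). The other 16 lists did not pass by camera, the lowest of their adjusted p-values being 0.105, for oxidative phosphorylation.

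**Figure D2:**
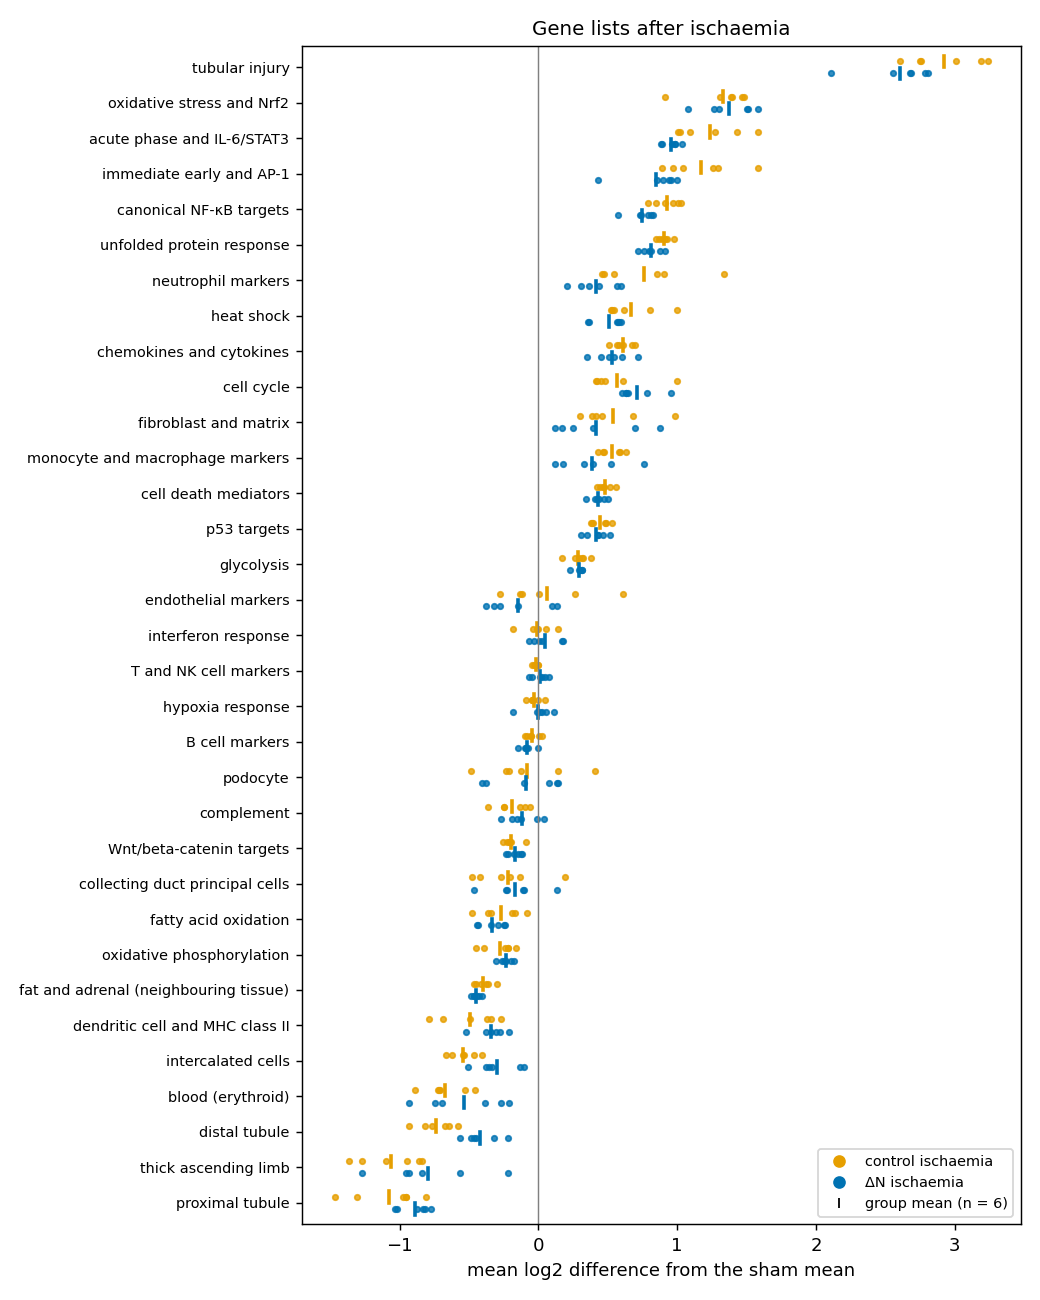
Mean log2 difference from sham of the members of each of 33 gene lists in single ischaemic control (orange) and ΔN (blue) kidneys; each point is 1 kidney, and the vertical ticks are group means of 6. Tubular injury genes have the largest mean rise (2.93 in control and 2.60 in ΔN kidneys), and proximal tubule genes the largest mean fall (-1.08 and -0.89).

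**Figure D3:**
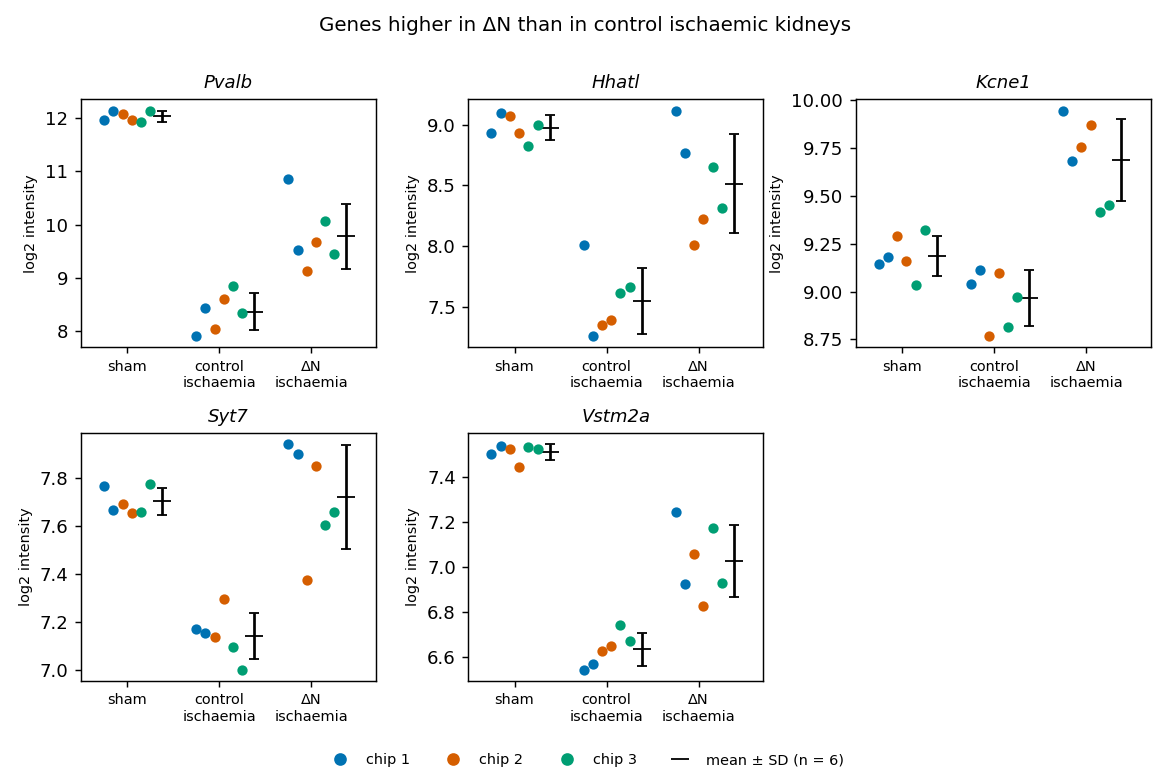
Log2 intensity of the 5 genes that differed between ΔN and control kidneys, in all 18 kidneys; points are single kidneys, coloured by array chip, and black bars are group means with SD. The mean of ΔN kidneys lies between those of control and sham kidneys for Pvalb, Hhatl and Vstm2a, at that of sham for Syt7 (7.72 against 7.70) and above it for Kcne1 (9.69 against 9.19).

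The ΔN kidneys also answer how far ischaemia with the inhibitor differs from sham. Since all sham mice are labelled wild type, ischaemia and genotype are not separated here. Havcr1 rose 130-fold (log2 7.02, SE 0.15, n = 6 per group), Lcn2 57.7-fold (5.85, SE 0.20), Krt20 42.6-fold (5.41, SE 0.18) and Timp1 31.7-fold (4.99, SE 0.19). The carbonyl reductase gene Cbr3 rose by 4.32 (SE 0.30), Sprr2g by 4.10 (SE 0.30, again against a sham mean below background), Sox9 by 4.05 (SE 0.32), Hmox1 by 3.94 (SE 0.19), Flnc at least 19.2-fold and Crct1 at least 9.91-fold. Nccrp1 fell (log2 -4.01, SE 0.29), as did Mep1b (-3.39, SE 0.22), Mettl7a2 (-3.16, SE 0.34), Egf (-3.12, SE 0.30), Fam107a (-3.10, SE 0.13), the steroid hydroxylase gene Cyp7b1 (-2.83, SE 0.37) and the oxygenase gene Fmo5 (-2.83, SE 0.20). Cox8b fell at least 8.50-fold, Cidea, a lipid droplet gene of brown fat, at least 7.22-fold and Adipoq, the fat hormone adiponectin gene, at least 5.49-fold. None of these 3 was above background in ΔN kidneys.

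Against sham, 11805 probes (26.1%) changed in ΔN kidneys, 5717 upward and 6088 downward, at 6261 genes. With 1 chip at a time 2431, 7265 and 6951 passed. Of the genes named in every comparison, Cxcl1 (3.53, SE 0.18), Icam1 (1.00, SE 0.08), S100a8 (1.82, SE 0.36) and Cxcl10 (0.59, SE 0.14, adjusted p = 0.00275) rose. Slc34a1 (-0.58, SE 0.06), Emx1 (-1.20, SE 0.09) and Ctnnb1 (-0.40, SE 0.13, adjusted p = 0.0231) fell. Ctnnb1 did not pass without ΔN replicate 1 or 2 or sham replicate 6 (adjusted p = 0.0618, 0.0542 and 0.0637). Nfkbia (0.21, SE 0.11, adjusted p = 0.190), Vcam1 (0.19, SE 0.14, adjusted p = 0.392), Tnfaip3 (0.11, SE 0.10, adjusted p = 0.470) and Umod (-0.01, SE 0.09, adjusted p = 0.979) did not pass. Ccl2 changed by 0.39 with an adjusted p of 0.00172, but no bound above 1-fold can be given, since it was not above background in sham.

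Of the 33 lists, 23 passed by camera against sham, 14 upward and 9 downward, and 7 did with an estimated correlation. Tubular injury (21 rose and 0 fell of 22, Tnfrsf12a at 3.30), NF-κB targets (18 rose and 1 fell of 31, Relb at 1.03), cell death mediators (9 rose and 1 fell of 18), Nrf2 targets (13 rose and 0 fell of 15), the unfolded protein response (9 rose and 2 fell of 15) and glycolysis (6 rose and 0 fell of 14) were raised, and proximal tubule genes (20 fell and 1 rose of 27) were lowered, by both forms of camera. Their adjusted p-values with an estimated correlation were 0.0167, 0.0338, 0.0438, 0.0167, 0.0224, 0.0438 and 0.0438. Adjusted over the list alone, 22, 20, 10, 15, 9 and 7 of the raised lists' members were higher, and 21 proximal tubule genes were lower. Neutrophil markers (5 rose and 0 fell of 19, adjusted p = 0.0703) did not pass, and fat with adrenal markers (4 fell and 0 rose of 11, adjusted p = 0.0271) were lowered, with adjusted p = 0.0782 with an estimated correlation.

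The size of the response to ischaemia was then compared between control and ΔN kidneys, both measured against the wild-type sham kidneys. At the probes that 3 controls had shown to change, the other controls differed from sham by 0.64 log2 in the direction of the change (SD 0.07 over 6 kidneys) and ΔN kidneys by 0.59 (SD 0.05, n = 6). The difference was -0.05, or -7.28% of the response, and ran from -0.09 to 0.02 over the 20 splits, of which 19 were below 0. These splits reuse the same kidneys and are not independent, so that their count is no measure of support. On the 3 chips the difference was -0.11, -0.03 and 0.01. It was -4.26% of the response without ΔN replicate 1, -4.23% without control replicate 3 and -2.66% without both outlying kidneys (control replicate 2 and ΔN replicate 1). ΔN replicate 1 had the lowest response of the ΔN kidneys (0.49) and control replicate 3 the highest of the controls (0.74). Leaving out either was thus bound to shrink the difference. Single control kidneys lay between 0.56 and 0.74 and single ΔN kidneys between 0.49 and 0.63. At the 13612 probes that all 12 ischaemic kidneys together showed to change, the difference was -0.04 (exact permutation test, p = 0.221). At probes raised and at probes lowered by ischaemia it was -7.29% and -7.26%. Probes that had changed at least 2-fold differed by -0.14, or -9.45%.

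Both comparisons with sham called 4890 probes upward and 5174 downward, and 0 in opposite directions by limma. Independent lists of these sizes would share 773 and 841. With sham kidneys split between the comparisons, 3438 and 3616 were shared on average, and at most 2 lay in opposite directions. Across probes, which are not independent replicates, the changes correlated at r = 0.968, against 0.310 in simulated groups with no effect that share the sham kidneys, and at 0.945 with the sham kidneys split. Their covariance was 0.309, against 0.00379 in the simulation, a difference of 0.305.

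**Figure D4:**
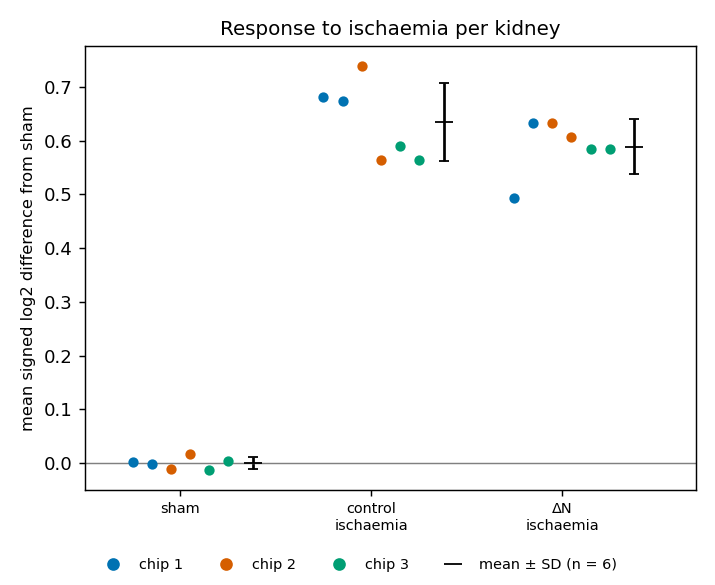
Mean signed log2 difference from sham of each kidney at the probes that ischaemia changes in the other controls; points are single kidneys, coloured by array chip, and bars are group means with SD. Control kidneys lie between 0.56 and 0.74 and ΔN kidneys between 0.49 and 0.63, with sham kidneys near 0.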

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

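The tests of the genes beside Ctnnb1 and Emx1, of Lars2, of the spread of Adipoq, Cox8b and Cidea in sham kidneys, of the NF-κB targets without the 2 outlying kidneys, and of the median of the adrenal markers were chosen only after the result was seen.

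NF-κB targets were lower in ΔN than in control kidneys by camera with the preset correlation and by fry (adjusted p = 0.0232), but not with an estimated correlation (adjusted p = 0.0556) or by the exact permutation test (adjusted p = 0.0893), and the 21 targets raised by ischaemia differed by -0.22 log2 (exact permutation p = 0.00866; -0.40, -0.16 and -0.09 on the 3 chips), being below the control mean in 6 of 6 ΔN kidneys. The 2 outlying ischaemic kidneys (control replicate 2 and ΔN replicate 1) are argued against as the whole cause, since the difference without them was -0.16 (exact permutation p = 0.0318). A block of NF-κB in tubule cells may contribute, as a hypothesis found and tested on the same kidneys, since the targets lay lower than 210 other genes raised by a like amount by -0.15 (exact permutation p = 0.00649; -0.24, -0.14 and -0.08 by chip; 6 of 6 ΔN kidneys). A milder injury as a whole stays open for part of the difference, as the matched genes themselves differed by -0.061 (exact permutation p = 0.245; lower in 5 of 6 ΔN kidneys), and by -0.02 without the outlying kidneys. Fewer white blood cells in ΔN kidneys stay open too, since the list means of neutrophil (-0.35) and macrophage markers (-0.14) were lower as well, as were those of immediate early (-0.33) and tubular injury genes (-0.32) against -0.18 for all NF-κB targets, though none of these 4 lists passed with an estimated correlation (adjusted p = 0.210, 0.472, 0.109 and 0.165).

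Among the 12 ischaemic kidneys, Anxa4, 22 measured genes from Emx1, differed by 0.89 with Cre (limma adjusted p = 0.00116, 8 kidneys against 4) and Gfpt1, 25 genes away, by -0.59 (adjusted p = 0.0418), while Lars2, 22 genes from Ctnnb1, stood at -0.83 with the ΔN allele and did not pass (adjusted p = 0.0919, 7 against 5). DNA carried along with either allele could do this. In a first test the 20 genes nearest to the locus did not stand out as a whole. Of all windows of 20 genes, 32.4% had as large a mean absolute t for the ΔN allele at Ctnnb1 and 8.40% for Cre at Emx1. Lars2, Anxa4 and Gfpt1 lie farther away than these 20 genes, so that the first test could not detect them. A second test, added once the first had been read and with Lars2, Anxa4 and Gfpt1 already noticed, placed 1 and 4 of the 20 genes with the smallest p among the 100 nearest to Ctnnb1 and Emx1, where random sets of genes hold 0.171 on average (hypergeometric exact p = 0.158 and 2.2e-05). For Emx1 the second test goes with linked DNA, but it was chosen with Anxa4 and Gfpt1 in view, and the first says nothing on these genes. A second bright Anxa4 probe stood at -0.20 with Cre and did not pass (limma adjusted p = 0.999), which alone does not decide for or against linked DNA. Linked DNA stays open for both loci. Hhatl, 6 genes from Ctnnb1, stood at 0.73 in carriers of the ΔN allele (limma adjusted p = 0.944). Its only carrier without Cre, control replicate 2, was the lowest ischaemic kidney (7.26, against 7.36 to 8.01 in the other controls and 8.01 to 9.12 in ΔN kidneys). That goes the other way from linked DNA, but 1 kidney cannot settle it. For Lars2, only 1 of the 12 kidneys of mice without both alleles lay at or below the highest ΔN kidney. That was control replicate 2, with the ΔN allele and no Cre (8.89, against 9.41 to 9.69). By the labels no other of these 12 mice carries the ΔN allele, so that the count cannot separate action of the truncated inhibitor from linked DNA. The low level without Cre goes against action of the inhibitor after Cre, but rests on 1 kidney, so that this stays open. Sham replicates 4 and 5 (9.91 and 9.85) lay below the other sham kidneys (10.61 to 10.83) and the controls without the ΔN allele (10.05 to 10.43) but above all ΔN kidneys. They were the lowest sham kidneys for Ctnnb1 too (12.20 and 12.40, against 12.62 to 12.80, and 11.85 to 12.35 in ΔN kidneys). This does not settle whether their label as wild type is right.

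Adipoq was at 9.21 in sham and at 6.53 in control and 6.38 in ΔN kidneys, Cox8b at 9.84, 6.49 and 6.43, and Cidea at 9.60, 6.67 and 6.63. The spread of these 3 genes in sham was at least 6.03 times the median SD of probes as bright. That cannot exclude loss of a kidney transcript after ischaemia, since a transcript that varies between sham kidneys could be lost as well, so that this stays open. Fat tissue left on sham kidneys may explain them. Of 14 further fat markers, listed before the test, 10 were above background in sham. All 10 were higher there than in both ischaemic groups, by a median of 1.28 log2 (Ucp1 8.87 against 6.45 and 6.46), and 8 were called lower in control kidneys by limma. Over the 6 sham kidneys their median correlation with Adipoq was 0.57, from -0.02 (Slc2a4) to 0.98 (Plin4). Cox8b and Cidea correlated with Adipoq at 0.73 and 0.63 (exact permutation p = 0.106 and 0.183). The conditions set before the test, on this median difference and this median correlation, were met. Fat tissue stays open, because 9 of the 10 markers were above background in both ischaemic groups too, so that they do not mark fat alone. Fabp4 and Plin1, both abundant in fat cells, were at background in sham (6.21 and 6.52, against a background of 6.75). They were no part of those conditions. Both were below background in control (6.21 and 6.33) and ΔN kidneys (6.26 and 6.32) too, so that they cannot tell absent fat from a probe without signal. Adrenal tissue as the source is argued against, since Star (6.26), Cyp11b1 (6.29), Cyp21a1 (6.41) and Hsd3b1 (6.13) were below background in sham, only 1 of 5 markers was above it and higher than in both ischaemic groups (Cyp11b2 7.08, against 6.89 and 6.90), and the median difference was 0.072 log2.

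When the kidneys were divided in 100 ways into groups of 6, chance could be excluded for control against sham (12375 probes, with at most 5053 by any other division) and for ΔN against sham (11805, with at most 3932), where 1 of the 100 divisions, the real one, called as many. It could not be excluded for ΔN against control, where 12 of the 100 divisions, which did not keep the chips balanced, called at least the real 5 probes. There 1 division called 2355 probes and 5 others 54 to 329, many times the real count, which points to a structure of the samples that was not tested further.

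A kidney far from the others of its group was found in 22 of 384 groups of 6 looked at (5.73%), and chance marks about 1 in 20 groups. Of the 22, 8 were in ΔN replicate 1. That kidney stood apart in Cdkn1a (log2 level 11.01), Mep1b (10.08), Slc4a1 (11.71), Sprr2f (8.11) and Sprr2g (9.09), in the mean differences from sham of the tubular injury list (2.11) and the immediate early list (0.43), and in the response to ischaemia (0.49). Control replicate 2 was far from its group for Cd14 (11.94) and for the Nrf2 list (0.91). Sham replicate 2 was far for Car14 (11.92) and Egf (13.34), and sham replicate 3 for the intercalated cell list (0.12). Control replicate 5 stood apart for Cox8b (6.71), replicate 3 for Cxcl1 (11.19), replicate 1 for H2-Eb1 (8.41), replicate 6 for the cell cycle list (1.00) and replicate 4 for the Wnt list (-0.090). ΔN replicate 4 stood apart for the glycolysis list (0.23) and Sdhb (12.16), ΔN replicate 6 for Col3a1 (7.33) and sham replicate 1 for Sdhb (12.61).

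Levels in ischaemic ΔN and control kidneys differed by limma for Pvalb (1.42), Hhatl (0.96), Kcne1 (0.72), Syt7 (0.58) and Vstm2a (0.39 as fitted). For Vstm2a the bound was at least 1.21-fold, since it was not above background in controls, and only 1 of its 2 other probes above background had the same sign. No ΔN sham mice were measured, so that a different response to ischaemia cannot be told from a genotype difference present without it. By camera with the preset correlation 17 lists differed, with the same limit. Of these, 0 passed with an estimated correlation and 0 by the exact permutation test of the list means after adjustment (7 of all lists at an unadjusted p under 0.05). The tool fry called 4. Of the 17, 6 were higher in ΔN kidneys: distal tubule (0.32), thick ascending limb (0.27), intercalated cells (0.24), proximal tubule (0.19), dendritic cells (0.15) and cell cycle (0.15). The 11 lower ones were neutrophil markers (-0.35), immediate early genes (-0.33), tubular injury (-0.32), acute phase genes (-0.28), endothelial markers (-0.21), NF-κB targets (-0.18), heat shock (-0.16), macrophage markers (-0.14), fibroblast genes (-0.12), the unfolded protein response (-0.092) and chemokines (-0.078).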

How the results depend on the processing

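Cyclic loess, centring on probes above background, leaving out both outlying ischaemic kidneys, the leave-one-out tests of the lists and of controls in the response, and the response at probes called in all 12 ischaemic kidneys were chosen only after seeing the data, while the other tests were planned. Fibroblast and matrix genes, lower in ΔN than in control kidneys, turned to higher with wild-type-labelled controls only (adjusted p = 0.796), and the cause was not tested. The counts against sham stayed within 1.5 times of 12375 and 11805 in every alternative but these. With 1 chip at a time, 4459, 7137 and 7284 probes passed for control and 2431, 7265 and 6951 for ΔN kidneys, with fewer arrays in each test, and with at least 1.5-fold changes 4704 and 4227 did. With each array left out the counts ran from 11527 to 12354 and from 10916 to 11645. With the chip as a block, median centring, a variance trend or only the groups compared in the fit, all 68 named genes in control against sham and all 61 in ΔN against sham stayed on their side of the threshold, and with wild-type-labelled controls only 66 of the 68 did.

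The 5 probes between ΔN and control kidneys became 0, 1 and 0 with 1 chip at a time, 2 with an offset of 50, 8 with a variance trend, 0 with only the 2 groups in the fit, 0 by Welch's test, 2 at an adjusted p under 0.01 and 3 with at least 1.5-fold changes. All 5 were higher in ΔN kidneys. With a variance trend 6 were higher and 2 lower. With wild-type-labelled controls only the 5 became 3, of which 1 was higher and 2 lower and none was among the 5. With controls of 1 allele only they became 2, of which 1 was higher and 1 lower (fewer arrays in both). With array position as a block they became 0. With each array left out they ran from 2, without control replicate 3, to 17, without control replicate 6 (14 higher and 3 lower). Sham kidneys spread less than control and ΔN kidneys (median SD 0.12 against 0.18 and 0.16 log2), which can lower the spread shared by all groups. In the simulation 20.3% of the calls were false in the fit on 18 arrays, and 8.98% in the fit on the 12 ischaemic arrays. The 5 calls of the fit on 18 arrays may thus rest in part on too small a spread. For settings other than the 2-group fit, fewer arrays or stricter thresholds, the cause was not tested. Adjusted p-values of the 5 genes in the 2-group fit ran from 0.130 to 0.427.

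With an estimated correlation, 9 of the 23 lists called in control against sham, 0 of the 17 in ΔN against control and 7 of the 23 in ΔN against sham passed. Of the 17, 10 were kept with wild-type-labelled controls only, 12 without both outlying kidneys and 15 with the chip as a block. For ΔN against control, fry called 4 and the exact permutation test of the list means 0, and the cause was not tested. The difference in response, ΔN minus control, was -0.05 log2 and, at probes changed at least 2-fold, -0.14, where the responses compared are larger. It ran from -0.06 to -0.03 with each array left out and was -0.02 (-2.66% of the response) without both outlying kidneys, of which ΔN replicate 1 had the lowest response of its group.

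The replicate numbers do not pair the kidneys. Pairs of like number correlated above 0.1 in 2, 3 and 2 of 6 cases. With the replicate number as a block the counts were 12478, 4 and 11944 probes, and 23, 16 and 23 lists, where the unfolded protein response between ΔN and control kidneys had an adjusted p of 0.0570.

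Signal over background limits what can be seen at dim genes, since 22288 probes (49.2% of all) lay above background, and a fold against a group at background is a lower bound.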

Other observations

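The tests of lists without single arrays were chosen only after the data had been seen, and the genes named were picked, with their values in view, from the 4 members of each list with the smallest p. Ischaemic ΔN kidneys differed from sham in 15 further lists. Cell cycle genes rose (16 up and 0 down of 24, camera adjusted p = 1.2e-07, and adjusted p = 0.0826 with an estimated correlation), among them the replication helicase genes Mcm5 (log2 2.51, SE 0.19), Mcm2 (1.65, SE 0.15) and Mcm3 (1.42, SE 0.11). Immediate early genes rose (14 up and 1 down of 18, adjusted p = 3.9e-07, and adjusted p = 0.101 with an estimated correlation), with Junb at 1.86 and Fosl2 at 1.16. Acute phase genes (12 up and 2 down of 22, Socs3 at 2.90), chemokines and cytokines (18 up and 4 down of 36, the macrophage growth factor gene Csf1 at 1.37), heat shock genes (8 up and 1 down of 13, Hspb1 at 2.68) and p53 targets (6 up and 2 down of 17, Gadd45a at 1.15) were raised as well. Their camera adjusted p-values were 1.2e-05, 8.9e-05, 0.00899 and 0.0174, and with an estimated correlation adjusted p = 0.0578, 0.0766, 0.0826 and 0.0826. Fibroblast and matrix genes (10 up and 3 down of 17, Col3a1 at 0.92 and Tnc at 1.45) and macrophage markers (11 up and 2 down of 22, Cd14 at 1.78) passed with adjusted p = 0.0214 and 0.0234, and had adjusted p = 0.474 and 0.436 with an estimated correlation.

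Lowered in ΔN kidneys against sham were genes of the thick ascending limb (8 down and 0 up of 13, Tmem207 at -2.02 and the tight junction gene Cldn10 at -0.68), oxidative phosphorylation (16 down and 1 up of 29, Sdhb at -0.76) and fatty acid oxidation (9 down and 3 up of 19, the thiolase gene Acaa2 at -1.05). Their camera adjusted p-values were 4.4e-04, 4.7e-04 and 0.00663, and with an estimated correlation adjusted p = 0.242, 0.164 and 0.213. Distal tubule (5 down and 0 up of 11, the magnesium channel gene Trpm6 at -0.56), intercalated cell (6 down and 0 up of 12), dendritic cell (5 down and 0 up of 14, H2-Eb1 at -1.02) and blood lists (4 down and 0 up of 7) passed with adjusted p = 0.0366, 0.0368, 0.0234 and 0.0293, and had adjusted p = 0.242, 0.286, 0.313 and 0.313 with an estimated correlation. Macrophage markers did not pass without ΔN replicate 2 (adjusted p = 0.0644), distal tubule genes without ΔN replicate 3 or sham replicate 3 (0.0559 and 0.0510), and intercalated cell genes without ΔN replicate 3 or 5 or sham replicate 3 (0.0591, 0.0558 and 0.0722). With only members that stand in no other list, intercalated cell genes and blood markers did not pass (adjusted p = 0.0840 and 0.0828).

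Lists without a call held genes that changed in both ischaemic groups by limma. Of the hypoxia genes, the vasodilator peptide gene Adm rose by 1.63 in control and 1.76 in ΔN kidneys (SE 0.19), while Egln1, an oxygen sensor of the hypoxia pathway, stood at -0.65 and -0.55 (SE 0.08) and Ndrg1 at -0.63 and -0.63 (SE 0.09). Of the Wnt targets, Axin2, a feedback inhibitor of the pathway, stood at -0.40 and -0.56 (SE 0.07) and the cyclin gene Ccnd1 at 0.33 and 0.48 (SE 0.07). In the interferon list Rsad2, an antiviral enzyme gene, stood at -1.26 and -1.14 (SE 0.14) and Ddx58, an RNA sensor gene, at 0.58 and 0.56 (SE 0.08). Serping1, which encodes the inhibitor of complement C1, stood at -0.93 and -1.19 (SE 0.20), and Tcf21, a podocyte transcription factor gene, at -1.38 and -1.26 (SE 0.19). The highest adjusted p among these values was 9.2e-04, for Serping1 in control kidneys. Among the lists without a call, median, mean and camera differed in sign for the interferon response in control against sham, for podocytes, fatty acid oxidation, p53 targets and hypoxia in ΔN against control, and for T and NK cells and hypoxia in ΔN against sham.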
